A study of Mus musculus with 16 samples.

How the data were processed

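Gene expression was measured in tibialis anterior muscle, a fast muscle of the lower leg, from the mouse offspring of dams that were fed normally or given 50% less food in week 3 of gestation. The offspring were fed ad libitum (AL) or calorie restricted (CR), which gives 4 groups, called control AL, control CR, undernourished AL and undernourished CR here. Each group had 8 mice whose RNA was combined in pairs, so that each of its 4 replicates is a pool of 2 mice hybridised to its own array, 16 arrays in all. The labels do not say which mice were pooled or whether they share a litter. The tests treat the pools as independent, which may not hold for maternal diet, since it was given to dams. Per the labels' protocols, total RNA was isolated with Trizol, treated with DNase, and 200 ng was labelled with the dye Cy3 for 1-colour Agilent mouse arrays.

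The authors deposited 1 scanner file per array. Per the file headers and the submitters' processing notes, Agilent Feature Extraction 10.5.1.1 made the values. The deposited intensity of a spot is its green processed signal, which per the file headers was background-subtracted and spatially detrended within the array and not normalized between arrays. The deposited files also hold other values per spot, among them the spot type and flags of 0 or 1 for a spot well above background, saturated or marked as an outlier. In the deposited files the processed signal of the CR arrays has 3 significant digits and that of the AL arrays 7. The authors also deposited a table of log2 values for the same arrays. Its source does not state its scale, so each pair of its columns was compared with the same pair of scanner files. The median of every probe over the 16 columns was 0, and differences between arrays followed the scanner differences with a median slope of 0.782 within a scan day and 0.831 between days, with a median intercept of -0.407 between days and a median correlation of 0.956 and 0.958 over probes. Direction and centring are thus known, and a log scale somewhat narrower than log2 of the scanner signal, while the authors' method of normalization is not given in the sources used here. In replicate order, its column medians were -0.0874, -0.0994, -0.0262 and -0.0037 in control AL, -0.0432, -0.0232, -0.0085 and -0.0084 in undernourished AL, 0.0264, 0.0297, 0.0301 and 0.0370 in control CR, and 0.0262, 0.0322, 0.0336 and 0.0167 in undernourished CR.

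Each array held 45018 spots, of which 43379 were not controls, for 41174 different probes. Control spots and spots marked as outliers (53 to 176 per array) were left out, no spot was saturated, and the 10 spots of each of the 245 repeated probes were averaged. Each array's 75th percentile of the processed signal, which ranged from 387 to 829, was subtracted on the log2 scale. Probes well above background on at least 4 arrays were kept, 32081 in all, and for each gene the probe with the highest mean over the 16 arrays was used. Probes were named by matching the RefSeq accession in the file to a table of NCBI's mouse annotation (assembly GRCm38.p6): 24844 probes matched and took 17178 different symbols, while 16330 did not match and kept the name the file gives. The test covered 24828 genes, of which 15020 had a symbol. Among called genes with further probes, a further probe was called in the opposite direction for 129 of 2132 genes in control offspring and 66 of 1299 in undernourished offspring when the diets were compared. Array signal limits the precision: 66.4% to 78.5% of spots were well above background.

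Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), 1 mean per group over all 16 arrays, and p-values were adjusted by Benjamini-Hochberg over the genes tested, with calls at an adjusted p under 0.05. Errors written after ± are standard errors of the log2 difference from that fit, with 4 arrays per group. All tests were two-sided. The 4 pairwise comparisons, the interaction of both diets and the mean effect of maternal diet were fixed before the data were examined, as were 37 gene lists for pathways, fibre types and other cell types of muscle. Lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists within a comparison. A list's value is the median log2 change of its measured members. Marker lists of brain, skin, liver and peripheral nerve were written after transcripts of brain and skin had been seen on the arrays, as was a list of 32 further brain genes, of which 26 were measured and 22 were well above background on all CR arrays. Genes were named by a fixed rule. In each comparison these are the 10 largest changes in each direction among called genes with a symbol whose arrays do not overlap between the groups, or, where none passed, the 5 smallest p-values in each direction. From each list the rule takes up to 4 called members with the largest change, or up to 2 with the smallest p where none passed. Other genes named were chosen after their values were seen and are said to be. Where no array of the dimmer group had any probe of a gene well above background, the change is given as at least N-fold: the brighter group's mean over its 4 replicates against the dimmer group's mean of, per array, the higher of the gene's own signal and the lowest signal well above background.

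The arrays lay on 4 slides of 4. Slide 1 held replicates 1 and 2 of both AL groups and slide 2 their replicates 3 and 4, and slides 3 and 4 held the CR groups in the same way. Both AL slides were scanned on 1 day and both CR slides on another, so that offspring diet and scan day cannot be told apart. Maternal diet was compared with the slide as a fixed block and within each slide, and offspring diet with the slide as a random block (within-slide correlation 0.137). The groups share replicate numbers, and the deviations of same-numbered arrays from their group means correlated in the AL groups (0.393, 0.123, 0.112 and 0.441 against a median of -0.0938 for other numbers), where numbers follow the slides. In the CR groups they were 0.226, 0.107, 0.0172 and 0.0584 against -0.0432, above that median but not all over 0.1, the bound set for pairing. Between diets they were -0.144 to 0.0764 against 0.0279 and 0.0109. Only the AL arrays were taken as paired. Alternatives covered quantile normalization, the filter on dim probes, every probe tested alone, the 2 groups of a comparison fitted alone, replicate block, slide block, array weights, a variance trend, the authors' deposited log2 values and each array left out in turn. Further alternatives, chosen after seeing the data, were normexp background correction of the median signal (offset 50), an index of brain transcripts as a covariate (alone and with the slide block), the fit without both control AL arrays of slide 1, and the fit without 5 arrays with raised skin or liver transcripts. The fit without these 5 arrays leaves 1 control AL array, so there every comparison that uses this group rests on a single array on that side. Files were read and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

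The fit was tested on simulated data with the real means and spreads of 24719 genes and 50 changed genes of each size. For a log2 change of 1 it called 50% of them between the AL groups, 58% between the CR groups, 48% between diets in control offspring and 66% in undernourished offspring. For a log2 change of 2 these shares were 96%, 92%, 92% and 88%. False calls were 2.4%, 3.7%, 9.15% and 2.96% of all calls. The simulated genes varied independently, with 1 spread per gene in all groups. Differences between arrays that many genes share, such as transcripts of other tissues, are not covered by these shares.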

Results

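The expression of 24828 genes in tibialis anterior was compared between offspring of normally fed and of undernourished dams, each fed ad libitum or calorie restricted, with 4 arrays per group and 16 in all. The first principal component of the normalized values held 57.3% of their variance and the second 10.3%. Beside muscle transcripts, the AL arrays carried transcripts of other tissues. The median log2 signal of 40 brain markers, relative to each array's 75th percentile, was 1.71, 1.26, -0.95 and -1.91 on the 4 control AL arrays and -0.94, -1.69, -1.85 and -3.24 on the undernourished AL arrays, against -6.42 to -5.91 on the 8 CR arrays. For the 18 measured skin markers it was 0.08, 1.17, -0.72 and -4.64 in control AL and -5.38, -5.46, -2.92 and -4.94 in undernourished AL. Skin markers were at -2.61 in undernourished CR replicate 2 and between -5.91 and -4.96 on the other CR arrays. The liver gene Alb, serum albumin, stood at -0.94 in undernourished AL replicate 3 and between -7.67 and -4.69 elsewhere. Of the brain markers, 20 were well above background on all CR arrays, as were 10 of the skin markers, and 2 brain markers also belong to the fixed lists.

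**Figure D1:**
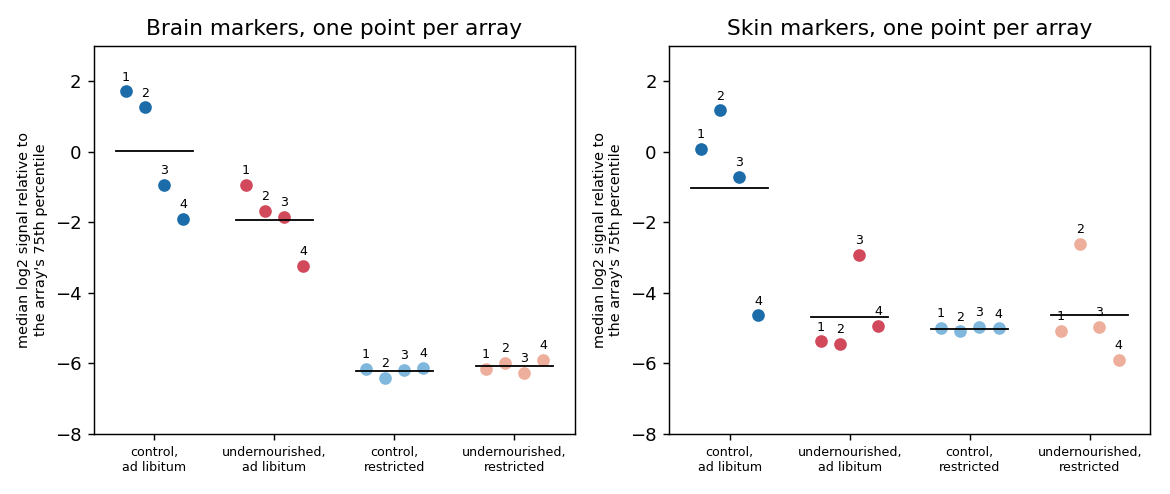
Median log2 signal of the brain markers (left) and of the skin markers (right) relative to each array's 75th percentile, 1 point per array, numbered by replicate, with a line at the group mean. Brain markers lay between -3.24 and 1.71 on the AL arrays and between -6.42 and -5.91 on the CR arrays.

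The first comparison asked how the muscle of control offspring differed between calorie restriction and ad libitum feeding. In restricted muscle, G0s2, which encodes an inhibitor of the lipase ATGL, rose by 3.28 ± 0.50 log2 units (adjusted p = 0.000302). On the control CR arrays it stood at 3.301 and 3.131 on slide 3 and at 0.8318 and 1.448 on slide 4. The control AL arrays ranged from -1.66 to -0.1081. Scd1, a stearoyl-CoA desaturase, and Fasn, the fatty acid synthase, rose by 1.73 ± 0.34 and 1.33 ± 0.29 (adjusted p = 0.00164 and 0.0032). The fatty acid synthesis list did not pass (median 0.15, adjusted p = 0.464), with 6 of 20 higher, 1 lower and 7 called adjusted over the list alone. Of the genes with the largest increases, the transcription factor Mafa rose by 2.75 ± 0.30 (adjusted p = 3.08e-05), Chrna9, an acetylcholine receptor subunit, by 2.78 ± 0.50, and Myod1, a master regulator of myogenesis, by 2.33 ± 0.41 (adjusted p = 0.000944 and 0.000739). In all, limma called 4259 genes higher and 3749 lower of 24828, 730 of them over 2-fold higher and 2243 over 2-fold lower.

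Of the fixed lists that passed the test upward, circadian clock genes had the largest median change, 0.68 log2 units. Of the list, 12 of 20 measured members were higher and 1 lower, and 13 were called adjusted over the list alone (camera adjusted p = 0.000349, and adjusted p = 0.727 with an estimated correlation). Its repressor genes Per3, Per2 and Cry1 rose by 2.10 ± 0.30, 1.87 ± 0.26 and 1.67 ± 0.19 (adjusted p = 0.000203, 0.000152 and 3.73e-05), and Usp2, a clock-controlled deubiquitinase, by 1.49 ± 0.21. Smooth muscle and pericyte genes rose by a median of 0.48, with 5 of 14 higher, 0 lower and 6 called adjusted over the list alone (adjusted p = 0.0058, and adjusted p = 0.727 with an estimated correlation). Smtn, a contractile protein of smooth muscle, rose by 1.46 ± 0.21 and the pericyte adhesion molecule Mcam by 1.22 ± 0.14. The smooth muscle call was lost under quantile normalization (adjusted p = 0.102) and without the arrays with raised skin or liver transcripts (0.0667).

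Further fixed lists rose by smaller amounts. Mitochondrial ribosome genes rose by a median of 0.31, with 18 of 69 higher and 18 called adjusted over the list alone (adjusted p = 0.000349), led by Mrps23 at 1.01 ± 0.15. Genes of the tricarboxylic acid cycle and pyruvate dehydrogenase rose by 0.34, with 9 of 21 higher and 9 called adjusted over the list alone (adjusted p = 0.0058), among them Ogdh, a subunit of oxoglutarate dehydrogenase, at 1.05 ± 0.19. Branched-chain amino acid catabolism rose by 0.35, with 6 of 20 higher, 1 lower and 7 called adjusted over the list alone (adjusted p = 0.0123), and its acyl-CoA dehydrogenase Acadsb rose by 0.81 ± 0.15. Cytosolic ribosomal proteins rose by 0.23, with 15 of 67 higher, 2 lower and 12 called adjusted over the list alone (adjusted p = 0.0058), and Rps25 rose by 0.75 ± 0.13. For each of these 4 lists, adjusted p = 0.923 with an estimated correlation. The proteasome list rose by a median of 0.19 (adjusted p = 0.0329, and adjusted p = 0.923 with an estimated correlation) but turned direction relative to other genes under quantile normalization (mean 0.01048), with 8 of 35 higher and 7 called adjusted over the list alone. It lost its call without control AL replicate 1 or 2 (adjusted p = 0.111 and 0.113) or control CR replicate 2 (0.226). Beside these 5 lists, the median change of the brain markers was -6.05 log2 units, with 37 of 40 lower and 1 higher, Camk2b, a gene named after its values were seen. With the brain index as a covariate none of the 5 lists was called (adjusted p = 0.295 for 4 of them and 0.867 for the proteasome), nor were the first 4 under quantile normalization (0.19 to 0.96). Without both control AL arrays of slide 1 (0.0829 to 0.561) and without the arrays with raised skin or liver transcripts (0.1 to 0.935) none of the 5 was called. In the latter fit the mitochondrial and cytosolic ribosome lists turned direction (means of -0.07 and -0.08). Of the other mitochondrial lists, respiratory complex I (adjusted p = 0.0521), complexes II to IV with ATP synthase (0.907), fatty acid oxidation (0.733) and mitochondrial regulators (0.969) did not pass, with 1, 3, 0 and 8 members called adjusted over the list alone.

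Fasting-response and PPAR target genes fell by a median of 0.82, with 1 of 20 higher, 10 lower and 11 called adjusted over the list alone (adjusted p = 0.00787, and adjusted p = 0.923 with an estimated correlation). Plin5, a lipid droplet protein of oxidative tissue, fell by 1.90 ± 0.37 (adjusted p = 0.00148), and Pdk4, the kinase that shuts off pyruvate dehydrogenase in fasting, fell by 2.97 ± 0.88 (adjusted p = 0.0187). Its signal split the control CR arrays by slide, at 3.062 and 3.972 on slide 3 and at 7.291 and 7.025 on slide 4. The control AL arrays stood at 8.047 to 8.539. The Pdk4 call was lost without control CR replicate 1 or 2 (adjusted p = 0.0625 and 0.0621) and with the brain index (0.0961). The list lost its call without a filter on dim probes (0.104). Muscle atrophy genes and FoxO targets fell by a median of 0.30, with 2 of 25 higher, 9 lower and 11 called adjusted over the list alone (adjusted p = 0.0344, and adjusted p = 0.923 with an estimated correlation). The muscle ubiquitin ligases Fbxo32 and Trim63 fell by 2.16 ± 0.55 and 1.78 ± 0.44 (adjusted p = 0.00771 and 0.00662), and the mTORC1 inhibitor Ddit4 by 2.20 ± 0.57. The atrophy list lost its call without control AL replicate 3 or 4 (adjusted p = 0.149 and 0.0541) or control CR replicate 1 or 4 (0.0634 and 0.0578), and under 5 other settings (0.0514 to 0.308).

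Leukocyte and macrophage genes fell by a median of 0.87, with 14 of 25 lower, none higher and 15 called adjusted over the list alone (adjusted p = 6.36e-05, and adjusted p = 0.764 with an estimated correlation). The macrophage protease Ctss fell by 1.78 ± 0.35 and the lysosomal protein Laptm5 by 1.43 ± 0.28 (adjusted p = 0.00164 and 0.00146), and the Ctss call was lost with the brain index (0.0848). Extracellular matrix genes fell by 0.60, with 10 of 28 lower and 10 called adjusted over the list alone, and tendon and cartilage genes by 1.26, with 7 of 14 lower, 1 higher and 9 called adjusted over the list alone (adjusted p = 0.000809 and 0.00378, and for both adjusted p = 0.923 with an estimated correlation). The fibrillar collagens Col3a1 and Col1a2 fell by 1.70 ± 0.40 and 1.66 ± 0.33, the cartilage collagen Col2a1 by 2.75 ± 0.41, and the tendon transcription factor Mkx by 1.53 ± 0.29. Schwann cell and nerve genes fell by a median of 1.1, with 9 of 15 lower and 10 called adjusted over the list alone (adjusted p = 0.000349, and adjusted p = 0.727 with an estimated correlation). The glial gene S100b fell by 2.58 ± 0.44. Beside these lists, the median change was -6.05 for the brain markers and -4.31 for the skin markers, with 16 of 18 skin markers lower. The peripheral nerve markers stood at a median of 0.20, with 2 of 5 lower, and liver markers at 0.20, with 1 of 14 higher and 1 lower.

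Among genes with a symbol, the largest decreases included those of neuronal genes. Nefl, which encodes the light chain of neurofilaments, was well above background on 1 of the 4 control CR arrays and changed by -9.20 ± 0.75 on the signals as measured (adjusted p = 5.82e-06), a size that rests in part on signals not well above background. Syt1, a calcium sensor of synaptic vesicles, changed by -8.89 ± 0.66 (adjusted p = 3.83e-06). Ptgds, a prostaglandin synthase of brain, fell by 8.88 ± 0.69, and Gria2, a glutamate receptor subunit also well above background on 1 of these 4 arrays, fell by 8.27 ± 0.60 in the same way. Gria1 and the brain proteoglycan Ncan were not well above background on any control CR array and were at least 191-fold and at least 290-fold lower there. Over the whole array 400 genes were over 16-fold lower and 1 was over 16-fold higher. These decreases moved with the brain markers, of which Nefl, Syt1, Gria1, Gria2 and Ncan are part.

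The number of genes called in control offspring was lower with the brain index and without 5 of the arrays. With the brain index as a covariate limma called 3406 genes, among them 1243 of the 4259 higher and 1715 of the 3749 lower genes. That index was 1, 0.794, 0.174 and 0.0988 on the control AL arrays and 0.00485 to 0.0055 on the control CR arrays. It thus follows this comparison, which widens the errors, so genes unrelated to brain RNA can lose their calls too. Without the 5 arrays with raised skin or liver transcripts 909 genes were called. That fit leaves 1 control AL array, which is assumed to vary like the other groups, so that the number of arrays fell together with the transcripts of other tissues. Mafa, Fasn, Per2, Cry1, Usp2, Col3a1, Col2a1, Nefl, Syt1, Gria1, Gria2, Ptgds and Ncan kept their calls there. The calls of G0s2, Scd1, Chrna9, Myod1, Per3, Smtn, Mcam, Mrps23, Ogdh, Acadsb and Rps25 were lost (adjusted p = 0.0509 to 0.227), as were those of Plin5, Pdk4, Fbxo32, Trim63, Ddit4, Ctss, Laptm5, Col1a2, Mkx and S100b (0.0536 to 0.285). The share of called genes that were higher, 53.2% here, was 62.9% after quantile normalization, 35.4% after normexp correction and 81.4% in the authors' log2 values, as the median change of all genes moved from 0.0648 to 0.159, -0.157 and 0.293.

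In undernourished offspring the same diets were compared to see how restriction acted after fetal undernutrition. G0s2 rose by 4.16 ± 0.50 log2 units in the restricted muscles (adjusted p = 0.000144), Scd1 by 2.77 ± 0.34 (adjusted p = 0.000167) and Fasn by 2.28 ± 0.29 (adjusted p = 0.000216). Retn, the adipokine resistin, rose by 2.01 ± 0.29, and Chrna9 and Fam78a by 2.37 ± 0.50 and 2.45 ± 0.40. Retn and Scd1 also belong to the fixed adipocyte list, which did not pass between diets in control or undernourished offspring. Whether the samples differed in fat tissue was not tested further. Gria2, well above background on 1 of the 4 undernourished CR arrays, and Syt1 fell by 6.90 ± 0.60 and 6.63 ± 0.66 (adjusted p = 2.34e-05 and 5.19e-05), and Nefl and Gria1 were at least 72.3-fold and at least 68.7-fold lower. Altogether 2590 genes were higher and 2449 lower, 494 over 2-fold higher and 1132 over 2-fold lower.

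Clock genes rose by a median of 0.44, with 9 of 20 higher, none lower and 11 called adjusted over the list alone (adjusted p = 0.00401, and adjusted p = 0.946 with an estimated correlation). Dbp, a clock output transcription factor, rose by 1.77 ± 0.28 and Per2 by 1.63 ± 0.26 (adjusted p = 0.000759 and 0.000845). Fatty acid synthesis genes rose by 0.41, with 7 of 20 higher, 3 lower and 10 called adjusted over the list alone (adjusted p = 0.0379, and adjusted p = 0.946 with an estimated correlation), and beside Scd1 and Fasn the rate-limiting carboxylase Acaca rose by 1.1 ± 0.23 and the lipogenic regulator Srebf1 by 1.13 ± 0.30. That list's call was lost without undernourished AL replicate 2 (adjusted p = 0.072), without undernourished CR replicate 1 (0.101) and under quantile normalization (0.212). Mitochondrial ribosome genes rose by 0.19, with 8 of 69 higher and 4 called adjusted over the list alone. Cytosolic ribosomal proteins rose by 0.23, with 10 of 67 higher, 1 lower and 9 called adjusted over the list alone (adjusted p = 0.00207, and adjusted p = 0.946 with an estimated correlation, for each). Mrps23 rose by 0.63 ± 0.15 and Rps26 by 0.88 ± 0.12. Without undernourished CR replicate 4 both calls were lost (adjusted p = 0.0519 and 0.0916), and quantile normalization ended the mitochondrial one (0.0794).

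Genes of fast glycolytic fibres fell by a median of 0.35, with 7 of 17 lower, none higher and 8 called adjusted over the list alone (adjusted p = 0.00401, and adjusted p = 0.946 with an estimated correlation). Tnnc2, the calcium-binding subunit of fast troponin, fell by 1.20 ± 0.20, and Myh4, the myosin heavy chain IIb, by 0.72 ± 0.13 (adjusted p = 0.00103 and 0.00162). After quantile normalization these calls were lost (adjusted p = 0.361 for the list, 0.0826 for Tnnc2 and 0.86 for Myh4). In the authors' log2 values the list turned direction, to a mean of 0.26 (adjusted p = 0.923). Atrophy and FoxO genes fell by 0.45, with 8 of 25 lower, 1 higher and 11 called adjusted over the list alone. Fasting and PPAR target genes fell by 0.85, with 9 of 20 lower, 1 higher and 12 called adjusted over the list alone (adjusted p = 0.00431 and 0.00536, and for both adjusted p = 0.946 with an estimated correlation). Gadd45a, a stress-induced gene of muscle atrophy, fell by 1.95 ± 0.31, Fbxo32 by 2.23 ± 0.55 and Plin5 by 1.82 ± 0.37 (adjusted p = 0.000836, 0.0113 and 0.0038), while Tfrc, the transferrin receptor, rose by 1.95 ± 0.33. Immediate early genes fell by 0.70, with 5 of 21 lower and 6 called adjusted over the list alone (adjusted p = 0.00536, and adjusted p = 0.946 with an estimated correlation), among them Egr2 at -0.89 ± 0.22 and Ccn1 at -0.89 ± 0.19.

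Extracellular matrix genes fell by a median of 0.38, with 6 of 28 lower and 8 called adjusted over the list alone (adjusted p = 0.00401, and adjusted p = 0.946 with an estimated correlation), and the membrane protease Mmp14 fell by 1.03 ± 0.24. Tendon and cartilage genes fell by 0.72, with 3 of 14 lower, 1 higher and 7 called adjusted over the list alone (adjusted p = 0.0379, and adjusted p = 0.946 with an estimated correlation), and Col2a1 fell by 2.38 ± 0.41. Schwann cell and nerve genes fell by 0.54, with 3 of 15 lower and 3 called adjusted over the list alone (adjusted p = 0.0102, and adjusted p = 0.946 with an estimated correlation). The tendon call was lost without undernourished AL replicate 1 or 2 (adjusted p = 0.0799 and 0.162), undernourished CR replicate 2 or 4 (0.159 and 0.0519) and with the brain index (0.0511), and the Schwann cell call without undernourished CR replicate 4 (0.0548). Glucocorticoid targets (median -0.74, adjusted p = 0.0379) and branched-chain amino acid catabolism (0.18, adjusted p = 0.0404) also passed, with 6 of 23 lower and 3 of 20 higher and with 7 and 3 called adjusted over the list alone, and adjusted p = 0.946 with an estimated correlation for both. The first was lost without undernourished AL replicate 2 or 3 (adjusted p = 0.0671 and 0.158) or undernourished CR replicate 1 or 3 (0.101 and 0.202), the second without undernourished AL replicate 1 or 2 (0.118 and 0.0671) or undernourished CR replicate 4 (0.239), under quantile normalization (0.282), with array weights (0.154) and with the brain index (0.11). The tendon and glucocorticoid calls were lost without the arrays with raised skin or liver transcripts (0.139 and 0.119). Beside these lists the brain markers fell by a median of 4.09, with 31 of 40 lower and 1 higher, while the skin markers stood at -0.06 with no member called and none called adjusted over the list alone. Liver markers stood at -0.50 with 3 of 14 lower, and peripheral nerve markers at -0.31 with 1 of 5 lower.

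The 8 lists that fell in undernourished offspring lost their calls with normexp correction (adjusted p = 0.0957 to 0.863) and without a filter on dim probes (0.137 to 0.436). Without the arrays with raised skin or liver transcripts the calls of Srebf1 and Fbxo32 were lost (0.109 and 0.0529), and in the authors' log2 values those of Egr2, Ccn1 and Mmp14 (0.0839, 0.141 and 0.103). Normexp correction called 13339 genes in place of 5039, of which 22.8% were higher, against 51.4% here, 62.4% after quantile normalization and 87.1% in the authors' log2 values. The median change of all genes was -0.00352 here, -0.245 with normexp, 0.0807 after quantile normalization and 0.241 in the authors' values.

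**Figure D2:**
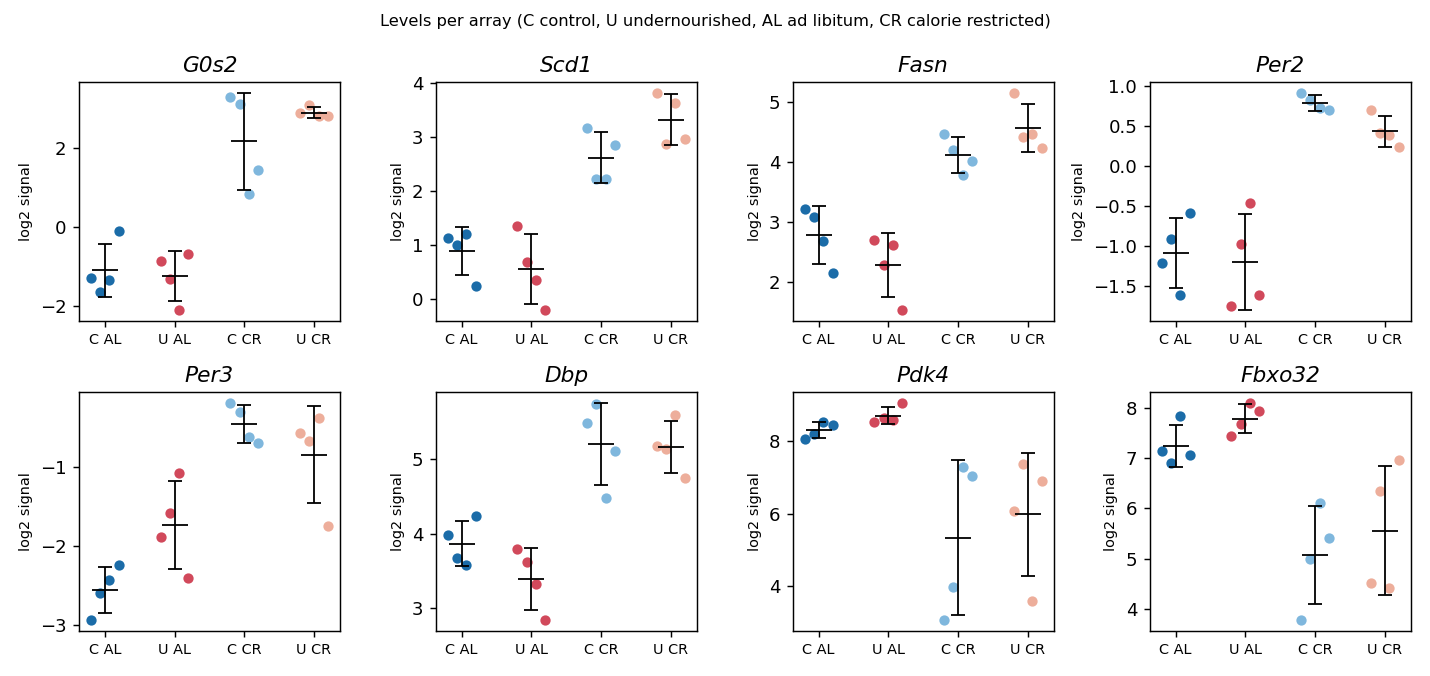
Log2 signal relative to each array's 75th percentile of 8 genes in the 4 groups (C control, U undernourished, AL ad libitum, CR calorie restricted), 1 point per array, with the group mean and standard deviation. G0s2, Scd1 and Fasn were higher and Fbxo32 was lower in the CR groups of both maternal diets.

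The responses to restriction in control and undernourished offspring, which share no arrays, were set against each other gene by gene. G0s2, Scd1, Fasn and Per2 rose in both, and Syt1, Gria2, Plin5, Fbxo32 and Col2a1 fell in both. The log2 changes correlated across the 24828 genes with a Pearson coefficient of 0.821 (jackknife SE over arrays 0.0674) and a Spearman coefficient of 0.717, and 77.0% of genes had the same sign; genes are not independent replicates. Called in both were 1927 higher and 1684 lower genes, where independent lists would share 444.3 and 369.8, and 7 genes were called in opposite directions. Both comparisons set the same scan days against each other, and brain markers were higher on the AL arrays of both, so the overlap of independent lists is not the value for 2 comparisons that share such a difference alone.

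**Figure D3:**
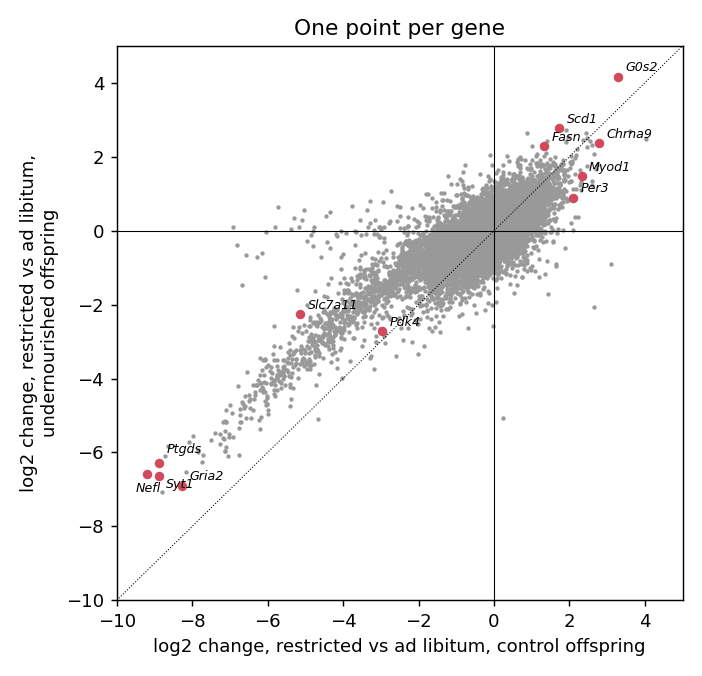
Log2 change between restricted and ad libitum feeding in control (x axis) and undernourished offspring (y axis), 1 point per gene, with 12 genes in red and a dotted line where both are equal. Of these 12, Nefl, Syt1, Ptgds and Gria2 lie lowest in both, and the Pearson coefficient is 0.821.

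The question named by the study's title is what undernutrition before birth does to muscle expression. In offspring fed ad libitum, Ptger4, a prostaglandin E2 receptor, rose by 1.48 ± 0.20 log2 units in undernourished against control mice (adjusted p = 0.0206). Sptlc3, a subunit of the enzyme that starts sphingolipid synthesis, was at least 1.11-fold lower (adjusted p = 0.000558), and Scel and Gjb5, genes of the epidermal cell envelope and of gap junctions, were at least 2.13-fold and at least 3.0-fold lower (adjusted p = 0.0315 and 0.0377). Krt76, an epithelial keratin, also passed, on the higher side (adjusted p = 0.00389), and Tmem150c on the lower side (adjusted p = 0.0477). Both AL groups were below background for these 2 genes, so both directions rest on signals that give no level. These 6 genes were part of 8 called, 3 higher and 5 lower, while 4795 genes had an unadjusted p under 0.05. The skin markers fell beside them by a median of 3.60 without a call over all genes. Adjusted over the list alone 16 of 18 were called, but the list was written after skin transcripts had been seen, so this is no independent support. Skin markers were raised on control AL replicates 1 to 3 (medians of 0.08, 1.17 and -0.72). Control AL replicate 4 stood at -4.64, below undernourished AL replicate 3 at -2.92.

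The maternal calls depended on single arrays and on the slide. The count of 8 became 2319 without control AL replicate 4, 49 without control AL replicate 3, and 2 without control AL replicate 1 or undernourished AL replicate 4. It was 4 or 5 without control AL replicate 2, any 1 control CR array or undernourished CR replicate 2 or 4, and 1514 with array weights. Sptlc3 and Krt76 kept their calls without any 1 array, and the Ptger4 call was lost without control AL replicate 1 or 2 (adjusted p = 0.0983 and 0.0792) or undernourished AL replicate 2, 3 or 4 (0.0672, 0.0629 and 0.0902). The Scel call held without control AL replicate 2, 3 or 4 or undernourished CR replicate 3 and was lost without each other array (0.0529 to 0.0983). The Gjb5 call held without control AL replicate 3 or 4 or undernourished CR replicate 1 or 3 and was lost without each other array (0.0551 to 0.124), and the Tmem150c call held without control AL replicate 3 or 4 or undernourished AL replicate 3 and was lost without each other array (0.0581 to 0.17). All 6 calls were lost with normexp correction (0.0608 to 0.953) and in the authors' log2 values (0.0638 to 0.155). A fit of the AL groups alone lost them as well (0.102 to 0.41). They were also lost without the arrays with raised skin or liver transcripts, but that fit leaves 1 control AL array. The number of arrays there fell together with the transcripts of other tissues. The AL arrays were taken as paired by replicate number. With the replicate block the Scel and Tmem150c calls were lost (0.0919 each). That block gives each number 1 effect shared by AL and CR arrays, so it is not a paired test of the AL arrays alone. With the slide as a block 1970 genes were called, 434 higher and 1536 lower, including all 8, and within slides 2700 were called on slide 1 and 1 on slide 2. Ptger4 changed by 1.62 within slide 1 and 1.34 within slide 2, and the other 5 have no size within slides, as at least 1 AL group was not well above background.

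Apart from the Schwann cell and nerve list, the called lists shifted by small amounts between the AL groups, and no member of any called list passed over all genes. Atrophy and FoxO genes rose by a median of 0.42 (23 of 25 positive, adjusted p = 0.0133), with 0 called adjusted over the list alone, and Gadd45a stood at 0.77 and Fbxo30, a ubiquitin ligase of atrophy, at 0.72. Proteasome genes rose by 0.21 (30 of 35 positive, adjusted p = 0.0027), tricarboxylic acid cycle genes by 0.21 (21 of 21, adjusted p = 0.00995) and branched-chain amino acid catabolism by 0.20 (17 of 20, adjusted p = 0.0133), each with 0 called adjusted over the list alone. Endothelial, smooth muscle and immediate early genes rose by 0.25, 0.23 and 0.39 (adjusted p = 0.0117, 0.0182 and 0.0182), with 2, 3 and 3 called adjusted over the list alone, the endothelial receptor Tek at 0.65, the smooth muscle myosin Myh11 at 0.75 and Fos at 1.56. For all of these, adjusted p = 0.839 with an estimated correlation. Schwann cell and nerve genes fell by 0.95 (4 of 15 positive, adjusted p = 0.002, 8 called adjusted over the list alone), cholesterol synthesis genes by 0.29 (7 of 22, adjusted p = 0.0117, 4). Leukocyte genes fell by 0.26 (6 of 25, adjusted p = 0.00528, 0), with S100b at -1.60, the sterol enzyme Hsd17b7 at -0.71 and the immune adaptor Tyrobp at -1.09, and adjusted p = 0.839 with an estimated correlation for each. Heat shock and autophagy genes rose by 0.21 and 0.23 (adjusted p = 0.0293 and 0.039), with 0 called adjusted over the list alone and adjusted p = 0.839 with an estimated correlation. Mitochondrial ribosome genes rose by 0.12 (adjusted p = 0.039, and adjusted p = 0.882 with an estimated correlation), with 0 called adjusted over the list alone, and turned direction relative to other genes after quantile normalization and in the authors' log2 values (means of 0.01002 and 0.01048). None of the 10 lists that rose was called after quantile normalization (adjusted p = 0.144 to 0.592) or with normexp correction (0.0507 to 0.639). In the authors' values only the endothelial one was (0.0432, the others 0.0558 to 0.677). The 3 lists that fell kept their calls in these settings. When the arrays with raised skin or liver transcripts were left out, most of the 13 calls were lost, but that fit leaves 1 control AL array. The number of arrays there fell together with the transcripts of other tissues. The tricarboxylic acid cycle (mean -0.07), heat shock (-0.09), leukocyte (-0.01) and mitochondrial ribosome lists (-0.20) then turned relative to other genes. On the control side these values rest on that 1 array.

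The brain markers moved beside these lists by a median of -1.77, with 34 of 40 called adjusted over the list alone, and the skin markers by -3.60. Liver markers stood at 0.34 and peripheral nerve markers at 0.13. These marker lists were written after brain and skin transcripts had been seen, so calls adjusted over such a list alone are no independent support. With the brain index as a covariate, the immediate early and leukocyte lists were the ones still called of these 13 (adjusted p = 0.00471 and 0.0061). Without undernourished AL replicate 4 the calls of the tricarboxylic acid cycle (adjusted p = 0.0551), endothelial (0.0768), smooth muscle (0.0558), immediate early (0.0551), atrophy (0.0551), heat shock (0.549), autophagy (0.0768) and mitochondrial ribosome lists (0.0768) were lost. Calls were also lost without control AL replicate 1 (mitochondrial ribosome 0.393, autophagy 0.0621), replicate 2 (mitochondrial ribosome 0.237, autophagy and endothelial 0.0509), replicate 3 (leukocyte 0.0609, immediate early 0.111, heat shock 0.148, mitochondrial ribosome 0.0697) and replicate 4 (atrophy 0.0667, autophagy 0.0982). They were lost without undernourished AL replicate 1 (mitochondrial ribosome 0.251), replicate 2 (mitochondrial ribosome 0.0609) and replicate 3 (atrophy and immediate early 0.0907, autophagy 0.0988). With the slide as a block Fbxo30, Tek, Myh11, Fos, S100b and Tyrobp were called (adjusted p = 0.00948 to 0.0431). The mitochondrial ribosome list was not called there (adjusted p = 0.0592), and its median was 0.39 within slide 1 and -0.15 within slide 2. Within slides 1 and 2 the Schwann cell list stood at -1.93 and -0.14, the tricarboxylic acid cycle list at 0.37 and 0.02, the proteasome list at 0.36 and -0.01, and the leukocyte list at -0.04 and -0.56.

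In calorie restricted offspring, undernourished and control mice were compared in the same way. No gene passed in limma: 0 were called, 715 had an unadjusted p under 0.05, the smallest adjusted p was 0.554, and testing every probe on its own called 1. Among the genes named by the rule, the smallest p-values belonged to Arhgef3, an exchange factor for RhoA, at 0.57 ± 0.11 and Larp6, a regulator of collagen mRNA, at 0.73 ± 0.16 on the higher side, and to Pag1, an adaptor of lipid rafts, at -0.60 and the metalloreductase Steap1 at -1.31 on the lower side, all with an adjusted p of 1.0. Pag1 and Steap1 were each well above background on 2 of the 4 undernourished CR arrays. Interferon-stimulated genes rose by a median of 0.19 (19 of 28 positive) and leukocyte genes by 0.26 (19 of 25 positive), each with an adjusted p of 0.0033, and atrophy and FoxO genes by 0.13 (23 of 25, adjusted p = 0.0106). Fast fibre genes fell by 0.10 (2 of 17 positive, adjusted p = 0.014) and endothelial genes by 0.07 (4 of 21, adjusted p = 0.017). For these 5 lists adjusted p = 0.989 with an estimated correlation, and 0 members were called adjusted over the list alone. The interferon sensor Ifih1 stood at 0.39, the macrophage lysozyme Lyz2 at 0.54, the stress gene Sesn3 at 0.50, the myosin kinase Mylk2 at -0.28 and the endothelial factor Sox18 at -0.59.

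Each of these 5 calls was lost without some single array. The interferon call was lost without undernourished CR replicate 2 or 3 (adjusted p = 0.0862 and 0.295) and the leukocyte call without replicate 3 of that group (0.0509). The atrophy call was lost without control CR replicate 1 (0.172) or undernourished CR replicate 2 or 4 (0.174 and 0.383). The fast fibre call was lost without control CR replicate 3 (0.165) or undernourished CR replicate 2 or 4 (0.25 and 0.109), and the endothelial call without control CR replicate 3 (0.135) or undernourished CR replicate 3 or 4 (0.0509 and 0.0594). Array weights ended the atrophy, fast fibre and endothelial calls (0.0517 to 0.141). The fit without the arrays with raised skin or liver transcripts ended the interferon, atrophy and fast fibre calls (0.189 to 0.277). Brain and skin markers stood beside them at -0.05 and 0.53, liver and peripheral nerve markers at -0.23 and -0.10, with 0 called adjusted over the list alone in each. With the slide as a block and within slides 3 and 4 the count of genes stayed at 0, and 5 lists were called on each slide.

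Over both offspring diets, the mean effect of maternal undernutrition was estimated, which a change in 1 feeding state alone can carry. Of the 9 lists called for it, only the atrophy list was also called in CR offspring. With the slide as a block, the tricarboxylic acid cycle, proteasome and cholesterol lists had CR medians of 0.0289, 0.0118 and 0.00872. Ptger4 stood higher at 0.99 and Sptlc3 lower, with no size since it was not well above background on any undernourished AL array (adjusted p = 0.0784 each), and Gulo, an enzyme of ascorbate synthesis, at 0.66 (adjusted p = 0.114). These 3 genes were called with the slide as a block (adjusted p = 0.0469 each). Within slides 1 to 4 Ptger4 stood at 1.62, 1.34, 0.18 and 0.82 and Gulo at 1.12, 0.72, 0.61 and 0.19. Limma called 0 genes, with 2609 at an unadjusted p under 0.05, 16 with the slide as a block, 5 higher and 11 lower, and 36 without control AL replicate 4. Atrophy and FoxO genes rose by a median of 0.22 and Schwann cell and nerve genes fell by 0.63 (adjusted p = 0.000957 each). With the slide as a block the Schwann cell list stood at -0.954 in AL but -0.0436 in CR offspring. Branched-chain amino acid catabolism rose by 0.15 (adjusted p = 0.0019) and the tricarboxylic acid cycle by 0.11 (adjusted p = 0.00531). For each of these 4 lists, adjusted p = 0.949 with an estimated correlation. The atrophy list kept its call with the brain index (adjusted p = 0.0176), without both control AL arrays of slide 1 (0.0127) and without any 1 array, whereas the other 3 lost it with that index (0.161, 0.0936 and 0.561). Proteasome, autophagy, mitochondrial ribosome, glucocorticoid and cholesterol lists completed the 9 called (medians 0.10, 0.13, 0.07, 0.22 and -0.09, adjusted p = 0.0123, 0.0142, 0.0332, 0.0440 and 0.0440). Each had 0 members called adjusted over the list alone and adjusted p = 0.949 with an estimated correlation, and lost its call with the brain index (0.124 to 0.845). Quantile normalization and the authors' values ended the tricarboxylic acid cycle, proteasome, autophagy, mitochondrial ribosome and glucocorticoid calls (0.229 to 0.934 and 0.223 to 0.847). Only the atrophy call held without the arrays with raised skin or liver transcripts, a fit that leaves 1 control AL array. There the mitochondrial ribosome and glucocorticoid lists turned direction (means of -0.07 and -0.06). The autophagy call was lost without control CR replicate 1 (0.0607) or undernourished CR replicate 4 (0.0541). The proteasome call was lost without control AL replicate 1 or 2, control CR replicate 1, undernourished AL replicate 1 or undernourished CR replicate 4 (0.0607 to 0.232). The mitochondrial ribosome call was lost without control AL replicate 1 or 2, control CR replicate 1, undernourished AL replicate 1, 2 or 4 or undernourished CR replicate 4 (0.0532 to 0.499). The cholesterol call was lost without those arrays, control CR replicate 2 or undernourished CR replicate 1 (0.0525 to 0.166). The glucocorticoid call held without control AL replicate 4, control CR replicate 3, undernourished AL replicate 1 or undernourished CR replicate 1 or 3 and was lost without each other array (0.0503 to 0.381) and with the slide as a block (0.0588). The brain markers stood at a median of -0.87 and the skin markers at -1.52 in this contrast.

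The maternal effects in the AL and CR states were set against each other gene by gene. Sptlc3 was the 1 gene called in the interaction (adjusted p = 0.022), with 2397 at an unadjusted p under 0.05. It has no size there, since it was not well above background on any undernourished AL array. Its call held without control AL replicate 3 or 4, control CR replicate 4, undernourished AL replicate 2 or undernourished CR replicate 3 or 4 and was lost without each other array (adjusted p = 0.0521 to 0.0945). It was also lost under 8 other settings (0.0529 to 0.814), the replicate block among them (0.0812). The slide block kept it (0.0329) and called 12 genes, and without control AL replicate 4 the count was 91. The log2 changes of both maternal comparisons correlated across genes with a Pearson coefficient of -0.00286 (jackknife SE 0.0854) and a Spearman coefficient of 0.0244, and 50.5% of genes had the same sign. Genes whose arrays did not overlap between maternal groups were 5.22% of all in AL and 2.73% in CR offspring, where chance gives 2.86%. Between diets they were 31.8% in control and 26.0% in undernourished offspring.

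In the interaction, the leukocyte list rose by a median of 0.55 (22 of 25 positive, adjusted p = 3.16e-05, and adjusted p = 0.622 with an estimated correlation), with Tyrobp at 1.47 and Ctss at 1.38. The endothelial list fell by 0.32 (adjusted p = 0.000436, and adjusted p = 0.622 with an estimated correlation), with the nitric oxide synthase Nos3 at -0.77 and the guidance receptor Robo4 at -0.57. Of their members 0 and 1 were called adjusted over the list alone. Both calls held without any 1 array and with the brain index (adjusted p = 2.43e-05 and 0.00204). The leukocyte one was lost without the 5 arrays with raised skin or liver transcripts, a fit that leaves 1 control AL array. In all 13 lists were called, 4 up and 9 down, beside brain markers at 1.78 and skin markers at 4.11. Of the skin markers 16 of 18 were called adjusted over the list alone, a list written after skin transcripts had been seen.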

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

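The tests of brain, skin and nerve transcripts, of the scan day and of both offspring diets in this part were chosen only after the result was seen. The counts over other splits of the arrays were planned. Single arrays stood apart in 2 of 156 sets of 4 arrays tested, where chance gives about 7.8. Fabp1, a fatty acid binding protein, was at -7.32 in control AL replicate 2 and between -8.07 and -7.96 in the other 3 arrays. Ssmem1 was at -6.50 in control AL replicate 4 and between -7.63 and -7.60 in the others. Neither gene was well above background on any of these arrays, so both gaps lie among signals that give no level.

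The effect of maternal diet differed between AL and CR offspring for 1 gene and 13 lists, by the interaction test. The gene was Sptlc3, at 2.41 on the signals as measured, which gives no size because it was not well above background on any undernourished AL array. Of the lists, the leukocyte list differed by a median of 0.552, the Schwann cell list by 0.575, cholesterol synthesis by 0.256 and the cell cycle by 0.0545. Medians were negative for the immediate early list (-0.479), developmental myosins (-0.331), heat shock (-0.33), the endothelial list (-0.32) and smooth muscle (-0.305). They were also negative for the clock (-0.274), the proteasome (-0.204), glycolysis (-0.192) and fast fibre genes (-0.184). The adjusted p ran from 3.16e-05 to 0.0449, and from adjusted p = 0.622 to 0.875 with an estimated correlation. Without any 1 array the leukocyte, endothelial, Schwann cell, cholesterol, smooth muscle and glycolysis calls held. The heat shock call was lost without undernourished AL replicate 4 (adjusted p = 0.0645), the proteasome call without control CR replicate 2 (0.0785) and the fast fibre call without undernourished CR replicate 2 (0.051). The immediate early call was lost without control AL replicate 3, undernourished AL replicate 3 or undernourished CR replicate 3 (0.064 to 0.0735). The clock call was lost without those arrays or control CR replicate 1 or 2 (0.0544 to 0.0868). The cell cycle call was lost without control AL replicate 3 or 4, control CR replicate 1 or 2, undernourished AL replicate 2 or 4 or undernourished CR replicate 4 (0.0533 to 0.244). The call of developmental myosins held without control AL replicate 2, control CR replicate 1 or 4, undernourished AL replicate 1, 2 or 3 or undernourished CR replicate 1 and was lost without each other array (0.0579 to 0.157). With the slide as a block the cell cycle and developmental myosin calls were lost (0.0578 and 0.0553). Quantile normalization ended 9 of the 13 calls (0.0798 to 0.569), leaving the leukocyte, endothelial, Schwann cell and cholesterol ones. All but the endothelial and cell cycle calls were lost without the arrays with raised skin or liver transcripts, a fit that leaves 1 control AL array.

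The first pattern is that of brain transcripts on the AL arrays. Syt1 averaged 2.23 in control AL and 0.22 in undernourished AL, against -6.66 and -6.41 in the CR groups. RNA of brain tissue in the AL samples may be the source. Over the 8 AL arrays, 26 further brain genes followed the index of the brain markers with a median correlation of 0.977. They were chosen as known brain genes and not by their values, and 21 were at 0.9 or more and the lowest at -0.707. Other genes, matched in signal to the brain markers and not to these 26, had a median of -0.267. On the log2 scale without the control AL arrays of slide 1 the medians were 0.826 and 0.117. Nerve inside the muscle is argued against as the whole source of the brain markers by 5 peripheral nerve markers. These changed with restriction by medians of 0.198 and -0.305 in control and undernourished offspring, against -6.05 and -4.09 for the brain markers. The 26 further brain genes changed less, by medians of -2.6 and -1.23. The fixed Schwann cell and nerve list fell by 1.1 and 0.54, with 9 and 3 of 15 lower. A part from nerve thus stays open, more so for the further brain genes. An effect of the scan day alike on all AL arrays is argued against as the whole source as well. The median of the brain markers ranged over 4.95 log2 units on these arrays and over 0.516 on the CR arrays. At most 1.06 was reached by 1000 random lists of genes of like signal. Those genes were drawn without regard to whether they vary together, so that comparison adds little. A part from the scan day stays open. An effect of feeding itself on these transcripts was not tested.

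The second pattern is that of the 1536 genes lower in undernourished AL offspring with the slide as a block, whose median change was -1.31. In CR offspring the median maternal change of these genes was -0.00484. They were chosen by their fall in AL offspring, and their signal was lower on the CR than on the AL arrays (median change -0.72 in undernourished offspring). Genes with little signal left on CR arrays cannot show a further fall. An effect of maternal undernutrition alike in both offspring diets is therefore not decided by that median. Unequal amounts of brain RNA may account for part of the second pattern, since the brain index moved the median in AL offspring to -0.611. With it 0 of these genes were called by limma, but an index that differs between the AL groups also widens the errors. The skin index moved this median to -0.908 with 1 gene still called, and both indices together to -0.56, so that skin RNA stays open. Over the 8 AL arrays both indices correlated at 0.793, so their shares cannot be well told apart. An effect of maternal undernutrition in AL offspring alone also stays open, untested.

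The third pattern is that of higher transcripts of named lipogenic and clock genes after restriction, 15 changes over both maternal diets with a median of 1.63. The fatty acid synthesis list did not pass in control offspring (median 0.151, adjusted p = 0.464). Brain RNA on the AL arrays is argued against as the whole cause of these 15, since with the brain index their median was 1.62, the lowest 0.98, and limma still called 14. Over all 34 changes called higher in both lists the median moved from 0.975 to 0.922 with that index, and 22 were still called. A difference between the scan days and an effect of restriction cannot be told apart, because 0 scan days hold both diets.

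Other splits of the same arrays were counted for each comparison. Between diets, of 35 splits only the real one, 1 split, gave as many genes. It gave 8008 in control offspring (highest other 2) and 5039 in undernourished offspring (highest other 0). The real split also parts the scan days and slides, and every other split mixes them on each side. The splits thus cannot tell diet from scan day, and they treat arrays of 1 slide as independent. Chance is not excluded for the list counts. There 9 of 35 splits gave as many as the 13 in control offspring (highest other 16). In undernourished offspring 11 of 35 gave as many as the 13 (highest other 20). For maternal diet in AL offspring chance is not excluded either. There 4 of 35 splits gave as many as 8 genes, the highest other 2157, and 9 of 35 as many as 13 lists, the highest other 17. The split with 2157 genes set control AL replicates 1, 2 and 3 and undernourished AL replicate 1 against the rest, which points to a structure of the samples, and the split along the slides gave 279. Of the 8 splits that part all pairs of replicate numbers only the real one gave as many, with at most 1 gene in the others. These 8 are too few for a share under 0.05, so they do not exclude chance. With the slide as a block the real split gave 1970 genes and the highest other 1587, 1 of 18 splits being as high, too few for a share under 0.05.

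In CR offspring the real count by limma was 0 genes, with 715 at an unadjusted p under 0.05, and all 35 splits must give at least that, so the splits test nothing there. The split along the slides gave the highest count, 228, against 0 with the slide as a block. For lists 31 of 35 splits gave as many as 5, the highest other 24. For the interaction 11 of 100 splits gave as many as 1 gene (highest other 50) and 23 of 100 as many as 13 lists (highest other 23). For the mean maternal effect 62 of 100 splits gave as many as 9 lists (highest other 24). Chance is not excluded for these list counts or for the interaction gene. The gene count of the mean effect was 0 by limma (2609 at an unadjusted p under 0.05), which all 100 splits must reach (highest other 29), so it is not tested either.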

How the results depend on the processing

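The settings with normexp correction of the median signal, with a brain index, without the control AL arrays of slide 1 and without the arrays with raised skin or liver transcripts were chosen only after the data were seen, as was the slide block with a brain index. The planned normexp correction of the mean signal was not run, since the files used here hold no such column. Over these settings the correlation of effects stayed between 0.787 and 0.852 for the diet comparisons and between -0.0446 and 0.0577 for the maternal ones. Counts of genes are by limma. With quantile normalization 16 genes were called for maternal diet in AL offspring and 1 for its mean effect, and lists numbered 4 in AL, 8 in CR, 5 for the interaction and 4 for the mean. Normexp called 0 genes in AL offspring (8 before, 4795 at an unadjusted p under 0.05), 0 for the interaction (2397) and 13339 for diet in undernourished offspring, with 3 lists in AL, 8 in CR, 21 for diet in control offspring and 5 for the mean. Without a filter on dim probes 12342 and 10075 genes were called for diet and 8 lists for maternal diet in CR offspring. With probes well above background on all arrays 2 genes were called in AL offspring and 0 for the interaction. Testing every probe alone called 1 in CR offspring, and fitting only the groups compared called 0 in AL. Array weights called 1514 genes in AL, 2 for the interaction, 13 for the mean and 3 lists in CR, and a variance trend called 0 for the interaction.

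The authors' values called 0 genes in AL offspring and 0 for the interaction, 13992 and 11848 for diet, and lists numbered 5 in AL, 9 in CR, 20 and 20 for diet, 7 for the interaction and 4 for the mean. With the brain index the counts were 5 genes in AL, 3406 for diet in control offspring, 0 for the interaction and 1 for the mean, and 4, 8 and 3 lists in AL, for diet in control offspring and for the mean. Without both control AL arrays of slide 1 they were 3, 4384, 0 and 1 genes and 5, 8 and 3 lists. Without the arrays with raised skin or liver transcripts they were 1 gene in AL and 909 for diet in control offspring, with 6, 8, 8, 6 and 4 lists in AL, in CR, for diet in control offspring, for the interaction and for the mean. The slide block called 1970 genes in AL, 12 for the interaction and 16 for the mean, and with the brain index 1 in AL and 1 for the mean. With the slide as a random block 6833 genes were called for diet in control and 3950 in undernourished offspring, 85.3% and 78.4% of the genes called without it being shared, and 40 calls of named genes were lost while 243 held. With an estimated correlation 0 lists were called in any comparison. The replicate block called 0 genes for the interaction in place of 1 and 6 in AL in place of 8, with 5 shared, and it changed the call of 17 of 390 named genes and of 0 of the 66 lists. That block gave each number 1 effect shared by AL and CR arrays, although the numbers were taken to pair arrays only within AL. The cause was not tested for these changes.

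Quantile normalization turned the mitochondrial ribosome list in AL offspring (mean 0.01002) and the proteasome list for diet in control offspring (0.01048) against the other genes. Normexp turned Ssmem1 for diet in control and undernourished offspring (-0.04362 and -0.1025), Mmp8 in undernourished offspring (-0.07955) and Pag1 in the mean (0.007202). The authors' values turned the mitochondrial ribosome in AL (0.01048), Cpt2 for both diet comparisons (0.07694 and 0.09014) and, for diet in undernourished offspring, fast fibre genes (0.2564), Atp5g3 (0.09193), Mdh2 (0.212), Slc25a4 (0.08707), Psma5 (0.1884), Eno3 (0.118), Myl3 (0.1967), Tnni2 (0.05661), Apln (0.05635) and Mcm7 (0.05089). The mitochondrial ribosome list turned in AL and in the mean with the brain index (-0.08294 and -0.02538), without the control AL arrays of slide 1 (-0.07881 and -0.02345), without the arrays with raised skin or liver transcripts (-0.1958 and -0.06608) and with slide block and brain index (-0.1731 and -0.07041). The last setting also turned the Schwann cell list in the interaction (0.1031). Without the arrays with raised skin or liver transcripts the tricarboxylic acid cycle (-0.06626), heat shock (-0.08866) and leukocyte lists (-0.01187) turned in AL. So did the mitochondrial (-0.07026) and cytosolic ribosome (-0.08313), Ndufa6 (-0.01442) and Hspb2 (-0.03179) for diet in control offspring, and glucocorticoid targets (-0.05623) and Dusp1 (-0.01355) in the mean. The cause was not tested.

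Leaving out each array in turn reversed no direction. Genes in AL offspring then ranged from 2 (without control AL replicate 1 or undernourished AL replicate 4) to 2319 (without control AL replicate 4). They were 49 without control AL replicate 3, 4 without control AL replicate 2 or control CR replicate 2 or 4, and 5 without control CR replicate 1 or 3 or undernourished CR replicate 2 or 4. Lists in AL ranged from 5 (without undernourished AL replicate 4) to 15. In CR offspring genes stayed at 0 and lists ranged from 5 to 10 (without undernourished CR replicate 1), with 8 without control CR replicate 2 or undernourished CR replicate 3 or 4 and 9 without control CR replicate 4. For diet, genes ranged from 6183 to 9067 and lists from 12 to 15 in control offspring, and from 3667 to 5851 and from 8 (without undernourished CR replicate 4) to 14 in undernourished offspring. Interaction genes ranged from 0 to 91 (without control AL replicate 4). They were 2 without control CR replicate 4, undernourished AL replicate 2 or undernourished CR replicate 4, and 0 without control AL replicate 1 or 2, control CR replicate 1, 2 or 3, undernourished AL replicate 1, 3 or 4 or undernourished CR replicate 1 or 2. Interaction lists ranged from 9 to 22 (without undernourished CR replicate 4). For the mean, genes ranged from 0 to 36 (without control AL replicate 4), with 2 without control AL replicate 3 and 1 without undernourished CR replicate 4. Its lists ranged from 4 (without control CR replicate 1) to 12, with 5 without control AL replicate 1 or 2 or undernourished CR replicate 4. The agreement of effects ranged from 0.773 to 0.846 between the diet comparisons and from -0.0404 to 0.0317 between the maternal ones. Spots well above background, 66.4% to 78.5% per array, limit what was measured.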

Other observations

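The genes in this part come from lists whose shift did not pass the test, and no test was added for them. Genes of the neuromuscular junction were among those that rose with restriction. Rapsn, which clusters acetylcholine receptors, rose by 0.98 ± 0.13 in control and 0.60 ± 0.13 in undernourished offspring (adjusted p = 0.000126 and 0.00576), and the receptor subunit Chrna1 rose by 0.75 ± 0.13 in undernourished offspring (adjusted p = 0.00185). Ache, the acetylcholinesterase, and Lrp4, the agrin receptor, rose by 1.0 ± 0.23 and 1.21 ± 0.24 in undernourished offspring (adjusted p = 0.00785 and 0.00375). In all, 6 and 4 of 17 members were higher, 0 lower, and 6 were called adjusted over the list alone in each comparison (list adjusted p = 0.0705 and 0.175). Of 16 slow fibre genes 2 were higher in each comparison: the calcium-binding protein Casq2 rose by 1.36 ± 0.20 and 1.67 ± 0.20 and phospholamban, Pln, by 0.92 ± 0.15 and 1.14 ± 0.15. The list stood at medians of -0.24 and -0.40 and did not pass (adjusted p = 0.906 and 0.921), with 2 and 3 called adjusted over the list alone. In control offspring 0 were lower, and in undernourished offspring 1, the myosin light chain Myl3, at -0.41 ± 0.13 (adjusted p = 0.0443). That call held without control AL replicate 1 or 4, control CR replicate 3, undernourished AL replicate 3 or undernourished CR replicate 3 and was lost without each other array (0.0509 to 0.123). It was lost under 4 other settings (0.0618 to 0.0916) and turned in the authors' log2 values (0.1967). Without the arrays with raised skin or liver transcripts the calls of Rapsn, Casq2 (control offspring) and Ache (undernourished offspring) were lost (adjusted p = 0.07, 0.0953 and 0.0546), and normexp correction ended that of Pln in control offspring (0.0633).

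Imprinted and redox genes were among those that fell. The imprinted genes Peg3, a zinc finger regulator, and Dio3, which inactivates thyroid hormone, changed by -1.10 ± 0.22 and -2.33 ± 0.27 in control and by -1.23 ± 0.22 and -1.17 ± 0.27 in undernourished offspring, and 5 of 22 members were lower and 1 higher in each, with 6 called adjusted over the list alone (list adjusted p = 0.095 and 0.238). Srxn1, a reductase of oxidized peroxiredoxins, changed by -1.12 ± 0.24 and -1.65 ± 0.24 (adjusted p = 0.00258 and 0.000448), and Hmox1, the inducible haem oxygenase, by -1.15 ± 0.24 in undernourished offspring (adjusted p = 0.00499). Of the antioxidant genes 3 of 31 were higher and 3 lower in control offspring, and 4 higher and 7 lower in undernourished offspring, with 6 and 11 called adjusted over the list alone (list adjusted p = 0.966 and 0.986). The Peg3 and Srxn1 calls in control offspring were lost without the arrays with raised skin or liver transcripts (0.249 and 0.186). Brain markers moved beside these genes by a median of -6.05 in control and -4.09 in undernourished offspring.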
